A study of Homo sapiens with 42 samples.

How the data were processed

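MCF-7aro cells and lines derived from them were profiled on 42 Affymetrix arrays. Per the labels' design text, the cells were parental without hormone or inhibitor (3 arrays), parental with testosterone (6), resistant to letrozole, anastrozole, exemestane or tamoxifen with testosterone (6 each), or testosterone-free resistant lines (LTEDaro, anastrozole and exemestane, 3 each). Per the labels' protocols, RNA was isolated with TRIzol, 5 ug of total RNA was labelled with biotin in one cycle, and cells were harvested from continuous culture with hormone or inhibitor; RNA of replicates was not pooled. The labels give no dose, no time in culture, no array date and no source of the replicates.

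The deposited values are log2 signals per probe set, made by the authors with RMA per the submitters' processing notes, which also name Partek; neither version is given. Which arrays were normalized together is not stated. The table held 22277 probe sets with values from 2.661 to 14.28; array medians lay between 6.477 and 6.574 and interquartile ranges between 3.181 and 3.659, so the values were used as deposited, with no further transformation.

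Of the probe sets, 62 are Affymetrix controls and were left out of the tests, 1043 carried several gene symbols and 2108 no gene, and these were not used here. The other 19064 carried 1 symbol, 19052 of them matched by Entrez number to the reference used for gene names and gene order. Of the 11963 genes, 4310 had more than 1 probe set, and each gene was represented by the probe set with the highest mean over all arrays. No intensity filter was applied. Some members of the gene lists, such as AREG, STAT1, HMGCR, LDLR and AR, had no probe set of their own and were not analysed here.

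One group-means model over all 42 arrays was fitted with limma 3.58.1 in R 4.3.3, with variances moderated towards a trend on intensity, so that all 9 groups share one estimate of the spread. Contrasts compared T_only with control; T_LET, T_ANA, T_EXE and T_TAM with T_only; LTEDaro, ANA_R and EXE_R with control; the inhibitors with one another, with and without testosterone; T_TAM with the mean of T_LET, T_ANA and T_EXE; the testosterone-free lines with one another; T_ANA with ANA_R and T_EXE with EXE_R; and, as interactions, these last differences with that of the parental cells and the exemestane against anastrozole difference with and without testosterone. P-values were adjusted by Benjamini-Hochberg over the 11963 genes within each comparison, and a gene was called at an adjusted p under 0.05. SE is the moderated standard error of the log2 difference. On these arrays the number of arrays limits the precision: with 200 genes changed in simulated data, 91% of 1.5-fold and 98.5% of 2-fold changes were recovered with 6 against 6 arrays, 74.6% and 94% with 6 against 3, and 67.2% and 86.6% with 3 against 3, and 13, 12 and 3 unchanged genes were called.

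Gene lists, contrasts, the rule for named genes and the alternative settings were fixed before the data were examined. The lists were estrogen-induced, estrogen-repressed and androgen-response genes; DNA replication, mitosis and cholesterol biosynthesis genes; interferon-response genes; HER and IGF receptor, ligand and adaptor genes; ERK-output genes; unfolded protein response genes; luminal and basal epithelial markers, mesenchymal and fibroblast markers and leukocyte markers; steroid hormone metabolism genes; drug efflux and detoxification genes; p53 target genes; apoptosis regulators of the BCL2 family; and hypoxia-response and glycolysis genes. They were tested with camera in limma at its preset correlation between genes of 0.01, adjusted over the 19 lists of a comparison, and again, likewise adjusted, with an estimated correlation and with fry. The estimated correlation includes what the genes share across the replicates of a group. Called members were counted, adjusted over all genes and the list alone. With 1 list raised in simulated data only it was called, settling no call lost with an estimated correlation.

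Named genes are, in each comparison with a control, the 6 called genes with the largest rise and the 6 with the largest fall among those with no overlap between the arrays of the groups compared and with a mean above the median of all genes (7) in the higher group; 4 each way in the other comparisons, with no condition on overlap for the interactions; up to 2 called members each way of each list; and CYP19A1, ESR1, PGR, TFF1, GREB1, ERBB2, EGFR, MKI67 and CCND1 in every comparison. Genes on the Y chromosome and XIST were left out.

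Calls shared by lines with one control were set beside 100 simulations of unchanged groups against the same control arrays, beside the product of the counts divided by the number of genes, and beside a split of T_only into replicates 1 to 3 and 4 to 6. Each comparison of groups was repeated with every other split of its arrays into groups of the same sizes, or 100 drawn at random where there were more, fitted on these arrays alone. Runs of 15 neighbouring measured genes in the reference order were scored by the median log2 difference and compared with 1000 shuffles of the gene order. Single arrays standing apart were sought among the key genes and list means with the Dixon ratio in groups of 6. Alternatives were the arrays of the compared groups only, a replicate block, a block of replicates 1 to 3 against 4 to 6, variance models without trend or robust to outlying genes, leaving out genes under the 40th percentile of the mean signal, the mean of all probe sets of a gene, leaving out probe sets with names ending in _x_at or _s_at, quantile normalization, centring each array on its median, array weights, leaving out each array in turn, and a 2-fold threshold. After seeing the data a random block within groups, for replicates 1 to 3 and 4 to 6, (limma's duplicateCorrelation) and fits with only replicates 1 to 3 or 4 to 6 of the resistant lines with testosterone were added.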

Results

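Transcript levels were measured on 42 Affymetrix arrays in MCF-7aro cells, a derivative of the estrogen receptor-positive breast cancer line MCF-7 that carries aromatase, the enzyme that turns androgens into estrogens. Parental cells were kept without hormone or inhibitor (control, 3 arrays) or with testosterone alone (T_only, 6 arrays). Lines resistant to letrozole, anastrozole, exemestane or tamoxifen were grown with testosterone and the drug (T_LET, T_ANA, T_EXE and T_TAM, 6 arrays each). The testosterone-free resistant lines, with 3 arrays each, were LTEDaro, a long-term estrogen-deprived line, and lines resistant to anastrozole (ANA_R) and exemestane (EXE_R). Letrozole and anastrozole are non-steroidal triazole inhibitors of aromatase, exemestane is a steroidal inhibitor, and tamoxifen binds the estrogen receptor. The labels state neither doses nor times in culture, so whether these were matched between the lines is unknown. They also do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision. Array medians lay between 6.48 and 6.57 on the log2 scale. All differences below are on that scale, where 1 unit is 2-fold. Except for interactions, the first genes named were picked among those with no overlap between the arrays compared, unless said.

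The control arrays and LTEDaro replicate 3 lay apart from all other arrays on the first principal component. On the second, most arrays of the lines resistant to aromatase inhibitors, EXE_R included, lay below those of T_only and ANA_R. The aromatase gene itself, CYP19A1, had a mean signal between 4.15 in T_EXE and 4.37 in T_ANA, near the lowest signals of the arrays in every group. It checks nothing here. LTEDaro replicate 3 correlated with the other LTEDaro arrays at a mean r of 0.9619 across genes. Its ESR1 signal was 9.33 against 12.18 and 11.99 in the other LTEDaro arrays. Within the resistant lines grown with testosterone, replicates 1 to 3 differed from replicates 4 to 6, with 189 genes called in T_LET, 17 in T_ANA, 771 in T_EXE and 207 in T_TAM, against 0 in T_only by limma (221 genes at an unadjusted p under 0.05). The ACTB signal near the 3' end of the transcript minus that near its 5' end, a measure of RNA quality, averaged -0.33 in the control, -0.28 in T_TAM, -0.18 in T_ANA, -0.16 in T_LET and T_EXE and -0.05 in T_only. It therefore moves with T_only in each comparison that holds it.

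**Figure D1:**
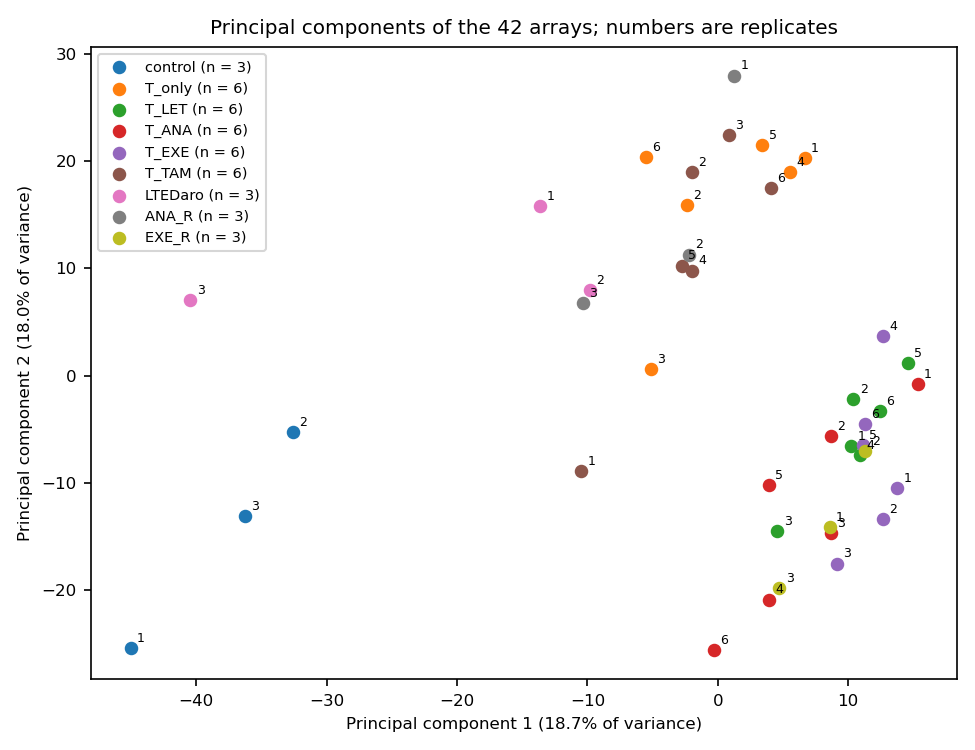
Principal components 1 and 2 of the 42 arrays (18.7% and 18% of the variance), each point an array coloured by group and numbered by replicate. The 3 control arrays and LTEDaro replicate 3 lie at the left, and EXE_R lies among the lines resistant to aromatase inhibitors with testosterone.

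Testosterone in parental cells addresses what the hormone, open to aromatase, does before resistance. The largest rises in T_only over control were those of the secreted protease gene KLK11 (5.18, SE 0.40, adjusted p = 2.73e-12), and of MGP (4.84, SE 0.52), an inhibitor of tissue calcification. They were followed by PDZK1 (4.45, SE 0.50) and CYP26B1 (4.32, SE 0.43), which degrades retinoic acid. SULF1 (3.81) and the transcription factor gene MYBL1 (3.54) also rose. The classical estrogen receptor targets GREB1 (3.13, SE 0.29), PGR (2.98, SE 0.39) and TFF1 (2.85, SE 0.18) rose, as did the cyclin D gene CCND1 (0.52) and the proliferation marker MKI67 (1.19). The largest falls were those of TAGLN (-3.98, SE 0.47, adjusted p = 2.49e-08), an actin-binding protein of smooth muscle, APOD (-3.64, SE 0.51), the hypoxia-inducible factor gene EPAS1 (-3.56, SE 0.41). NT5E (-3.48) TNS3 (-3.32) and L1CAM (-3.29) followed. The receptor genes EGFR (-2.12) and ERBB2 (-0.61) fell. ESR1, the estrogen receptor gene, was not called (0.29, widened SE 0.28).

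By gene list, all 36 measured mitosis genes rose, among them BUB1 (2.44) and ASPM (2.42) (mean 1.57, adjusted p = 3.09e-35, and p = 0.0827 with an estimated correlation). Of 41 estrogen-induced genes, 25 rose and 1 fell, the latter CCN5 (-2.99) (adjusted p = 2.57e-11, and p = 0.0827 with an estimated correlation). The cholesterol biosynthesis genes rose in 15 of 18, with HMGCS1 (1.07) and MSMO1 (1.04) as examples (adjusted p = 2.32e-07, and p = 0.0827 with an estimated correlation). Of 34 DNA replication genes 18 rose, CDC6 (1.10) and MCM10 (0.98) among them, and 1 fell, the cyclin gene CCNE1 (-0.69) (adjusted p = 8.34e-06, and p = 0.435 with an estimated correlation). The estrogen-repressed genes fell in 4 of 12, TGFB2 (-2.53) among them, and 1 rose (adjusted p = 0.0369, and p = 0.435 with an estimated correlation), a call lost without control replicate 2 or T_only replicate 1 or 5 (adjusted p = 0.0948, 0.0592 and 0.0548). Among 19 androgen-response genes none rose and 5 fell, such as PMEPA1 (-1.60) and ELL2 (-0.76) (adjusted p = 0.0319, and p = 0.14 with an estimated correlation), a call lost without control replicate 1 (adjusted p = 0.0619).

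Further lists called lower were the ERK-output genes, with 7 of 19 lower such as PHLDA1 (-2.16) and EGR1 (-2.06) and 1 higher, CCND1, the mesenchymal and fibroblast markers, with 8 of 19 lower such as SNAI2 (-3.07), and the drug efflux and detoxification genes, with 7 of 23 lower such as CYP1A1 (-2.64) and HMOX1 (-1.97) and 1 higher, GCLC (0.29). Their adjusted p were 0.00182, 0.000735 and 0.00583, and p = 0.121, 0.14 and 0.14 with an estimated correlation. The remaining lists were not called. Members higher and lower were 1 and 2 of 31 interferon-response genes, 3 and 6 of 21 HER and IGF genes, 3 and 4 of 21 unfolded protein response genes, with XBP1 (1.12) up and ATF3 (-2.51) down, and 7 and 3 of 18 luminal markers, with AGR2 (3.50) highest. For basal markers they were 2 and 7 of 15, leukocyte markers 0 and 1 of 13, steroid hormone metabolism 2 and 3 of 21, p53 targets 5 and 3 of 16, apoptosis regulators 1 and 4 of 13, and hypoxia and glycolysis genes 6 and 4 of 19. Adjusted over the list alone, 25 estrogen-induced genes rose and 3 fell. In all, 3918 of 11963 genes were called, 2156 higher and 1762 lower in T_only, 581 of them at least 2-fold. The count was 2437 without control replicate 1, and the share of called genes that was higher, 55%, was 42.4% with each array centred on its median.

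**Figure D2:**
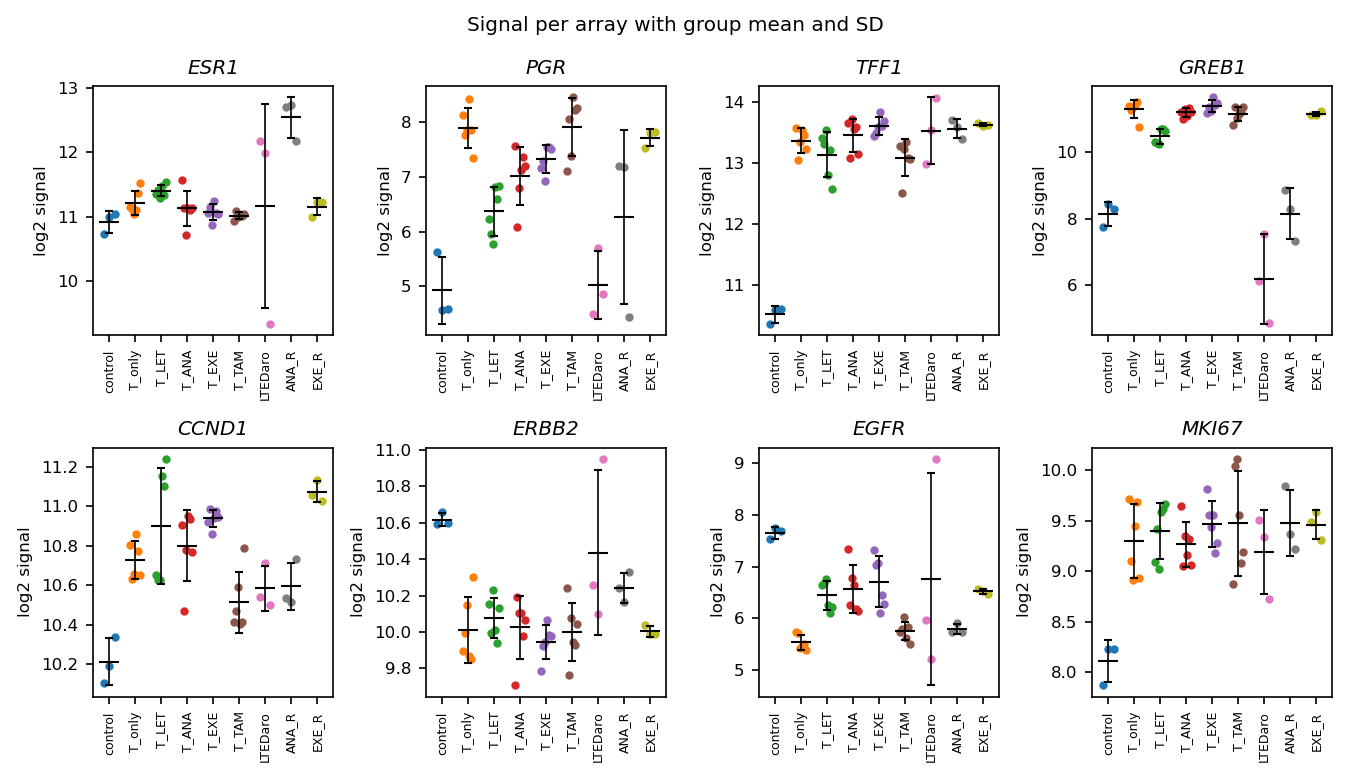
Signal of 8 genes on each array (log2, vertical axis, each panel with its own range) by group (horizontal axis); points are arrays, and bars give the group mean and SD. TFF1 means lay between 13.08 and 13.62 in every group but the control, where the mean was 10.52, and GREB1 was lowest in LTEDaro at a mean of 6.18.

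Resistance with testosterone was read against T_only, with the hormone but no drug, so resistance and drug exposure cannot be separated. In T_LET, AKR1C3 (4.04, SE 0.41, adjusted p = 2.45e-09), an aldo-keto reductase that makes testosterone, rose most. It was followed by the carbonic anhydrase gene CA2 (3.42, SE 0.34), the gap junction gene GJA1 (3.33, SE 0.50), the prostaglandin E synthase gene PTGES (3.11, SE 0.30), ITM2A (2.81) and the secreted SCUBE2 (2.63). Among the largest falls were those of SLC6A14 (-4.62, SE 0.71, adjusted p = 6.84e-06), SATB1 (-3.15, SE 0.29), ELOVL2 (-3.11, SE 0.34), ABCA12 (-3.09, SE 0.37), BLNK (-2.92) and TM4SF1 (-2.79). PGR (-1.53, SE 0.32) and GREB1 (-0.81, SE 0.23) fell, and TFF1 (-0.23, SE 0.15) and ESR1 (0.19, SE 0.23) were not called. DNA replication genes rose in 29 of 34, with GINS2 (1.24) (adjusted p = 1.32e-20, and p = 0.194 with an estimated correlation). Unfolded protein response genes fell in 13 of 21, DNAJB9 (-2.35) and DNAJC3 (-1.15) among them, and 1 rose, XBP1 (0.61) (adjusted p = 1.64e-06, and p = 0.2 with an estimated correlation). ERK-output genes rose in 10 of 19, such as PHLDA1 (1.83), and 1 fell, IER3 (-1.36), while p53 target genes fell in 8 of 16, such as TP53I3 (-0.92) (adjusted p = 0.021 and 9.08e-05, and p = 0.293 and 0.194 with an estimated correlation). Mitosis genes rose in 7 of 36, such as MAD2L1 (0.72) (adjusted p = 0.0248, and p = 0.91 with an estimated correlation), a call lost without T_only replicate 3 or 6 or T_LET replicate 2 or 5 (adjusted p = 0.0969, 0.337, 0.063 and 0.0746). The estrogen-induced genes moved both ways, 11 up such as PTGES and STC1 (2.27) and 8 down such as BCL2 (-1.75), and the list was not called. In all, 2954 genes were called, 1595 higher and 1359 lower, 214 of them at least 2-fold.

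In T_ANA against T_only, PTGES (3.58, SE 0.30, adjusted p = 2.16e-10) and CA2 (3.13, SE 0.34) rose by the most among genes with no overlap between arrays, and GJA1 by 3.59. Also up were BMP7 (2.00, SE 0.29), STC1 (1.94, SE 0.32), SCUBE2 (1.86) and GPRC5A (1.74). SLC6A14 (-3.81, SE 0.71, adjusted p = 0.000127), ABCA12 (-3.14, SE 0.37), ELOVL2 (-2.94, SE 0.34), BLNK (-2.63), TM4SF1 (-2.58) and NUCB2 (-2.29) were among the largest falls. PGR (-0.88, SE 0.32) fell, a call lost without T_only replicate 1, 4 or 5 or T_ANA replicate 2 or 3 (adjusted p = 0.0655, 0.0834, 0.0514, 0.101 and 0.0652). GREB1 (-0.10, SE 0.23), TFF1 (0.09, SE 0.15) and ESR1 (-0.09, SE 0.23) were not called. AKR1C3 (2.06) rose here too. DNA replication genes rose in 23 of 34, such as MCM2 (0.98), and ERK-output genes in 10 of 19, such as EGR1 (1.60) (adjusted p = 2.15e-10 and 0.000687, and p = 0.427 and 0.275 with an estimated correlation). Unfolded protein response genes fell in 11 of 21, such as DNAJB9 (-1.62), and rose in 2, and p53 target genes fell in 6 of 16, such as SESN1 (-0.79) (adjusted p = 0.00033 and 0.00033, and p = 0.427 and 0.283 with an estimated correlation). Estrogen-induced genes rose in 15 of 41 and fell in 2, the latter IRS1 (-0.99) and PGR (adjusted p = 0.01, and p = 0.812 with an estimated correlation). In all, 3659 genes were called, 1974 higher and 1685 lower, 184 of them at least 2-fold. With replicates 1 to 3 only of the resistant lines with testosterone, chosen after seeing the data, 1719 were called.

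In T_EXE against T_only, PTGES (3.96, SE 0.30, adjusted p = 1.86e-11) and CA2 (3.34, SE 0.34) were among the largest rises, as was GJA1 (3.64), whose arrays overlap between the groups. Also up were SLC1A1 (2.57, SE 0.23), MAOB (2.29, SE 0.31), RASGRP1 (2.17) and GULP1 (1.94). Among the largest falls were those of SLC6A14 (-4.00, SE 0.71, adjusted p = 0.000114), ELOVL2 (-3.54, SE 0.34), NUCB2 (-2.76), DKK1 (-2.62, SE 0.32), BLNK (-2.52) and VAV3 (-2.19). PGR (-0.57, SE 0.32), GREB1 (0.10, SE 0.23) and TFF1 (0.24, SE 0.15) were not called. Estrogen-induced genes rose in 16 of 41, such as PTGES and EGR3 (1.80), and fell in 2, AGR2 (-1.52) and IRS1 (-0.82) (adjusted p = 5.41e-07, and p = 0.283 with an estimated correlation). Estrogen-repressed genes fell in 4 of 12, such as BLNK and EFNA1 (-0.86) (adjusted p = 0.00435, and p = 0.364 with an estimated correlation). DNA replication genes rose in 17 of 34, such as MCM2 (0.81) and MCM7 (0.67), cholesterol biosynthesis genes in 7 of 18 (1 fell), such as HMGCS1 (0.81), and ERK-output genes in 7 of 19 (1 fell), such as EGR1 (1.38) and EPHA2 (1.18). These lists had adjusted p = 1.14e-10, 0.000522 and 0.000909, and each had an adjusted p = 0.283 with an estimated correlation. Unfolded protein response genes fell in 11 of 21, and p53 target genes in 3 of 16 (adjusted p = 2.65e-06 and 0.0159, and p = 0.283 and 0.373 with an estimated correlation). The interferon-response list was called higher on 2 of 31 genes, ISG15 (1.68) and USP18 (1.09) (adjusted p = 0.00366, and p = 0.694 with an estimated correlation), a call lost without T_EXE replicate 5 (adjusted p = 0.209). In all, 1875 genes were called, 917 higher and 958 lower, 170 of them at least 2-fold. With a random block within groups 1173 were called, and 915 with replicates 4 to 6 only of the resistant lines with testosterone, both alternatives chosen after seeing the data.

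In T_TAM against T_only, the gap junction gene GJA1 (3.46, SE 0.50) and TEX14 (3.43, SE 0.15, adjusted p = 2.08e-19) rose most, and also up were GDAP1 (2.98, SE 0.19), SPINK4 (2.37, SE 0.13), PPM1E (2.26, SE 0.22) and RLN2 (2.24). The largest falls were those of KLK11 (-3.91, SE 0.33, adjusted p = 3.31e-11), MGP (-3.82, SE 0.42), ABCA12 (-3.25, SE 0.37), SERPINA3 (-2.90), SLC26A2 (-2.58) and IGFBP5 (-2.39). PGR (0.02, SE 0.32), GREB1 (-0.14, SE 0.23), TFF1 (-0.28, SE 0.15) and ESR1 (-0.20, SE 0.23) were not called. p53 target genes fell in 11 of 16, such as CDKN1A (-0.95), and this call held with an estimated correlation (adjusted p = 3.43e-08 and 0.0425). DNA replication genes rose in 24 of 34, such as MCM2 (0.93), and cholesterol biosynthesis genes in 7 of 18 (1 fell), such as TM7SF2 (1.11) (adjusted p = 2.82e-15 and 4.42e-05, and p = 0.157 and 0.161 with an estimated correlation). Unfolded protein response genes fell in 9 of 21, such as DNAJB9 (-1.37) (adjusted p = 1.4e-06, and p = 0.157 with an estimated correlation). Interferon-response genes rose in 6 of 31, and none fell (adjusted p = 0.00195, and p = 0.697 with an estimated correlation), a call lost without T_TAM replicate 4 (adjusted p = 0.074). Luminal epithelial markers fell in 6 of 18 (1 rose), such as MUC1 (-1.62) (adjusted p = 0.00131, and p = 0.137 with an estimated correlation). Of the estrogen-induced genes 11 rose, RET (1.55) among them, and 9 fell, BCL2 (-1.74) and EGR3 (-1.64) among them, and the list was not called. In all, 2243 genes were called, 1115 higher and 1128 lower, 176 of them at least 2-fold. With a random block within groups 1494 were called, and 1469 with replicates 1 to 3 only of the resistant lines with testosterone, both alternatives chosen after seeing the data.

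The resistant lines with testosterone shared T_only as control, so their differences share its chance values. T_LET and T_ANA had 2106 genes called in the same direction, T_LET and T_EXE 1335, T_ANA and T_EXE 1420, T_LET and T_TAM 1287, T_ANA and T_TAM 1240, and T_EXE and T_TAM 847. Simulated unchanged groups have few calls to share, and shared at most 1 gene. Independent draws of the same numbers of calls for T_LET and T_ANA would share 263.2 higher and 191.4 lower genes. With T_only split to give each line its own arrays, the same pairs shared 1051, 665, 705, 674, 602 and 295 genes, but a shift of all T_only arrays would remain. The covariance of the log2 differences was 0.1045 for T_LET and T_ANA and 0.044 for T_EXE and T_TAM, against 0.0085 and 0.0086 in the simulations and 0.0955 and 0.0402 with the split control. All 3 lines resistant to aromatase inhibitors had 589 genes higher and 584 lower, 34 and 49 of them at least 2-fold in each. With T_TAM added the numbers were 321 and 350. Among the 2-fold genes of all 3 inhibitor lines were PTGES and CA2, which were higher, and ELOVL2, SLC6A14, BLNK and ABCA12, which were lower (ABCA12 by -3.09, -3.14 and -2.45).

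The testosterone-free lines were read against the control, which also held no hormone. In LTEDaro, GALNT12 (3.48, SE 0.27, adjusted p = 4.97e-12), which starts mucin-type glycosylation, ELAPOR1 (3.67, SE 0.56), CEACAM6 (3.52, SE 0.62), HOPX (3.11) and TFF1 (3.01, SE 0.21) rose. CCN5 (-4.14, SE 0.58), PLS3 (-3.87), COL5A1 (-3.55, SE 0.38), MAOB (-3.55), FBN2 (-3.34) and L1CAM (-3.27) fell. GREB1 (-1.97, SE 0.33) fell while TFF1 rose, and PGR (0.10, SE 0.45) and ESR1 (0.24, SE 0.33) were not called. Without LTEDaro replicate 3 ESR1 was higher by 1.163 (adjusted p = 3.99e-07). All 36 mitosis genes rose, such as HMMR (1.96), as did 27 of 34 DNA replication genes (1 fell), such as GINS1 (1.75), and 10 of 18 cholesterol biosynthesis genes, such as IDI1 (1.04) (adjusted p = 6.98e-34, 7.13e-18 and 5.63e-08, and p = 0.0933, 0.122 and 0.0933 with an estimated correlation). Estrogen-induced genes moved both ways, 13 up such as AGR2 (2.87) and 7 down such as CA12 (-2.37), and the list was not called with all arrays. It was called higher without LTEDaro replicate 3 (mean 0.408, adjusted p = 5.48e-05) or control replicate 2 (adjusted p = 0.0449). Without LTEDaro replicate 3 luminal markers were also called higher (adjusted p = 0.00719) and basal markers, mesenchymal markers and unfolded protein response genes lower (adjusted p = 0.0162, 0.00379 and 0.0104). In all, 2578 genes were called, 1318 higher and 1260 lower, 500 of them at least 2-fold. Fitted on the 6 arrays of LTEDaro and the control alone, 606 genes were called, and 1707 with a random block within groups, chosen after seeing the data.

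In ANA_R against control, CYP26B1 (4.29, SE 0.50, adjusted p = 3.24e-08) rose most, followed by RLN2 (3.54, SE 0.43), GALNT12 (3.29), CCDC170 (3.19, SE 0.37), PKIA (3.09) and TFF1 (3.04, SE 0.21). APOD (-4.28, SE 0.58), PLS3 (-4.28), CCN5 (-4.22, SE 0.58), TAGLN (-3.97, SE 0.54), SELENOP (-3.87) and MAOB (-3.80) fell most. ESR1 (1.62, SE 0.33) and PGR (1.34, SE 0.45) rose, and GREB1 (0.00, SE 0.33) was not called. PGR lay at 7.20, 7.18 and 4.43 in ANA_R replicates 1 to 3, so its rise rests on replicates 1 and 2. Its call was lost without control replicate 2 or 3 or ANA_R replicate 1 or 2 (adjusted p = 0.0877, 0.0966, 0.24 and 0.205). CCDC170 and ESR1 lie beside each other, and 11 of the 15 genes measured from SASH1 to ESR1 were called higher. All 36 mitosis genes rose, such as DLGAP5 (3.02), as did 32 of 34 DNA replication genes (1 fell), such as CCNE2 (1.88), and 14 of 18 cholesterol biosynthesis genes, such as IDI1 (1.39) (adjusted p = 8.42e-41, 2.57e-21 and 1.37e-08, and p = 0.0571, 0.0696 and 0.0696 with an estimated correlation). Estrogen-induced genes rose in 24 of 41, such as MYBL1 (2.85), and fell in 4, such as CCN5 and BCL2 (-2.48) (adjusted p = 1.57e-07, and p = 0.153 with an estimated correlation). ERK-output genes fell in 8 of 19 (1 rose), such as EPHA4 (-2.39) and DUSP5 (-2.13), and unfolded protein response genes in 8 of 21, such as ATF3 (-3.56), and rose in 3, XBP1 (1.67) among them. The adjusted p of these lists were 0.00266 and 0.00465, and p = 0.142 and 0.267 with an estimated correlation. p53 target genes fell in 6 of 16, such as GADD45A (-2.53), and basal epithelial markers in 7 of 15 (2 rose), such as ACTA2 (-1.93) (adjusted p = 0.00496 and 0.0117, and p = 0.167 and 0.153 with an estimated correlation). Mesenchymal markers fell in 6 of 19 and drug efflux genes in 7 of 23, with 1 up (adjusted p = 0.00266 and 0.0107, and p = 0.164 and 0.153 with an estimated correlation). HER and IGF signalling genes fell in 7 of 21 and rose in 2 (adjusted p = 0.0419, and p = 0.153 with an estimated correlation), a call lost without control replicate 2 or 3 or ANA_R replicate 1 or 2 (adjusted p = 0.0882, 0.0541, 0.0545 and 0.0838). Estrogen-repressed genes fell in 5 of 12 and rose in 2 (adjusted p = 0.0363, and p = 0.291 with an estimated correlation), a call lost without control replicate 2 or ANA_R replicate 2 (adjusted p = 0.0791 and 0.0934). Leukocyte markers fell in 2 of 13 (adjusted p = 0.0451, and p = 0.284 with an estimated correlation), a call lost without control replicate 1 or ANA_R replicate 1 (adjusted p = 0.173 and 0.128). In all, 3013 genes were called, 1729 higher and 1284 lower, 672 of them at least 2-fold.

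**Figure D3:**
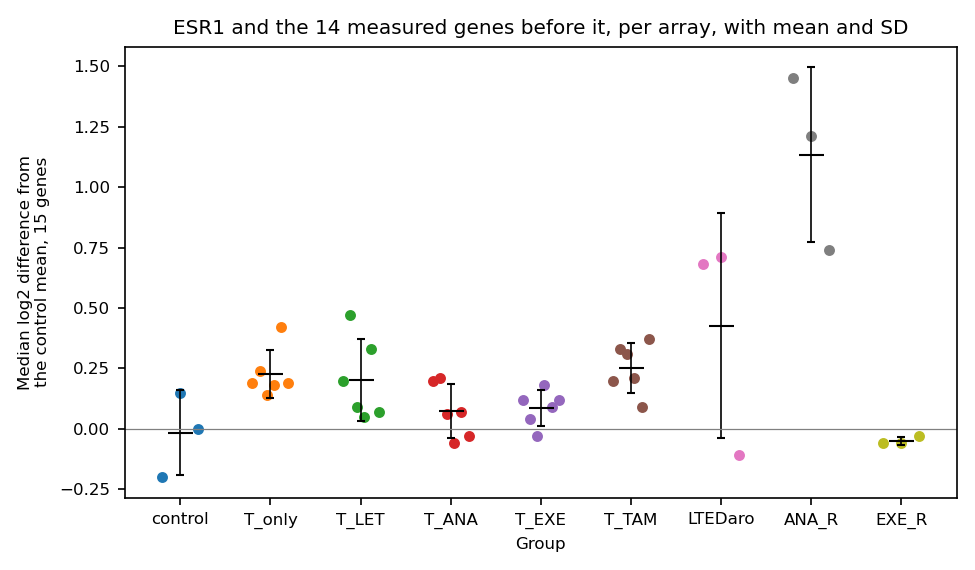
Median log2 difference from the control mean (vertical axis) of ESR1 and the 14 measured genes before it in the gene order, on each array (points) by group (horizontal axis), with group mean and SD. The ANA_R arrays lie at 1.45, 1.21 and 0.74, LTEDaro replicates 1 and 2 at 0.68 and 0.71, and LTEDaro replicate 3 at -0.11.

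In EXE_R against control, PDZK1 (6.06, SE 0.58, adjusted p = 5.73e-10), GJA1 (6.06, SE 0.71), MGP (6.03, SE 0.60), MYBL1 (5.36, SE 0.48), EGR3 (4.63, SE 0.33) and KLK11 (4.11, SE 0.47) rose most. DKK1 (-4.00, SE 0.45, adjusted p = 1.68e-08), EPAS1 (-3.82, SE 0.48), TAGLN (-3.75), SELENOP (-3.57), APOD (-3.46) and L1CAM (-3.45) fell most. All of the estrogen receptor targets GREB1 (3.00, SE 0.33), PGR (2.80, SE 0.45) and TFF1 (3.11, SE 0.21) rose, in cells grown with no testosterone, as did CCND1 (0.86). ESR1 itself was not called (0.23, SE 0.33). Estrogen-induced genes rose in 30 of 41 and fell in 1, and the list's call held with an estimated correlation (adjusted p = 1.07e-23 and 0.00745). Estrogen-repressed genes fell in 8 of 12, such as TGFB2 (-2.75) and EFNA1 (-1.80), and BCL6 (1.16) rose (adjusted p = 6.83e-05, and p = 0.133 with an estimated correlation). All 36 mitosis genes rose, such as BUB1 (2.23), as did 14 of 18 cholesterol biosynthesis genes, such as EBP (1.25), and 27 of 34 DNA replication genes (1 fell), such as MCM10 (1.45) (adjusted p = 3.43e-36, 3.93e-10 and 9.34e-16, and p = 0.0312, 0.0312 and 0.133 with an estimated correlation). The unfolded protein response genes fell in 6 of 21, such as ATF3 (-2.84), and XBP1 (1.35) rose (adjusted p = 0.00599, and p = 0.331 with an estimated correlation). Mesenchymal markers fell in 5 of 19 (adjusted p = 0.019, and p = 0.319 with an estimated correlation), a call lost without control replicate 1 or EXE_R replicate 2 (adjusted p = 0.163 and 0.0611). In all, 2385 genes were called, 1298 higher and 1087 lower, 568 of them at least 2-fold.

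The testosterone-free lines shared 1721 calls in one direction between LTEDaro and ANA_R, 1220 between LTEDaro and EXE_R, and 1495 between ANA_R and EXE_R, with covariances of 0.1877, 0.1256 and 0.1722. Simulated unchanged groups, with few calls to share, had 0 shared calls and a covariance of 0.0172. Independent draws would share 190.5 higher and 135.2 lower genes for the first pair, 143 and 114.5 for the second, and 187.6 and 116.7 for the third. The 3 control arrays could not be split into separate controls. In all of LTEDaro, ANA_R and EXE_R, 589 genes were higher and 486 lower, 113 and 107 of them at least 2-fold.

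**Figure D4:**
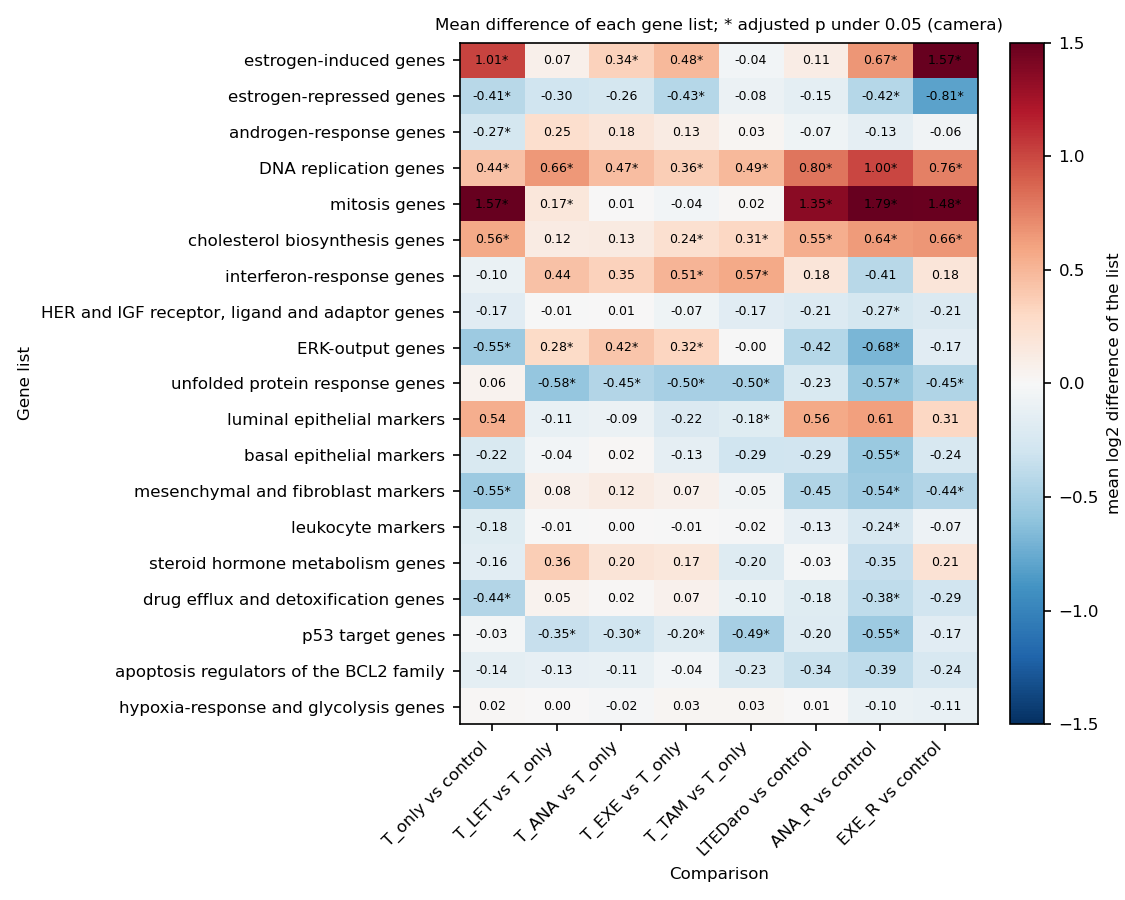
Mean log2 difference (colour and printed value) of each gene list (vertical axis) in the comparisons with a control (horizontal axis); an asterisk marks an adjusted p under 0.05 by camera with its preset correlation. Mitosis genes had means of 1.57 with testosterone alone and 1.35, 1.79 and 1.48 in LTEDaro, ANA_R and EXE_R, against -0.04 to 0.17 in the resistant lines with testosterone read against T_only.

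Letrozole and anastrozole, both non-steroidal triazoles, were compared in lines grown with testosterone. HEY1 (0.98, SE 0.18, adjusted p = 0.00598), a Notch target, PHACTR2 (0.84, SE 0.15), which binds actin, and WDR43 (0.72) were higher in T_LET. AHNAK2 (-1.22, SE 0.24) and the chloride channel gene CLIC3 (-0.88, SE 0.16) were lower. AKR1C3 (1.97) was higher in T_LET, and the estrogen-induced gene RAPGEFL1 (-0.74) was lower. PGR (-0.65, SE 0.32, adjusted p = 0.323), ESR1 (0.27, SE 0.23) and TFF1 (-0.32, SE 0.15) were not called, with intervals of 2 SE either side from -1.29 to -0.01, -0.19 to 0.74 and -0.62 to -0.02. GREB1 (-0.72, SE 0.23, adjusted p = 0.122) was not called either, with an interval from -1.19 to -0.25. The estrogen-induced list was lower by a mean of -0.27 (adjusted p = 0.000462, and p = 0.807 with an estimated correlation), with 3 of 41 members called. The DNA replication and mitosis lists were called higher with 0 members called by limma and 10 and 3 members at an unadjusted p under 0.05 (adjusted p = 8.01e-07 and 0.00238, and p = 0.807 and 0.807 with an estimated correlation), the mitosis call being lost without T_ANA replicate 6 (adjusted p = 0.183). In all, 106 genes were called, 51 higher and 55 lower in T_LET, 9 of them at least 2-fold. The count was 50, 59, 55, 34 and 37 without T_LET replicates 1, 2, 4, 5 and 6, and 200, 165, 47, 65 and 45 without T_ANA replicates 1, 2, 3, 5 and 6. It was 1073 with array weights, and 11 with a random block within groups, 13 with replicates 1 to 3 only and 576 with replicates 4 to 6 only, chosen after seeing the data.

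Exemestane, the steroidal inhibitor, differed from anastrozole in lines with testosterone by higher CPE (1.57, SE 0.29, adjusted p = 0.00282), a peptide-processing enzyme gene, MAN2A1 (1.10, SE 0.15), a glycan-trimming enzyme gene, and ME1 (0.93). The stress-activated kinase gene MAPK13 (-1.18, SE 0.18), KCNK5 (-0.85) and WWOX (-0.70) were lower in T_EXE. IGF1R (0.72), the receptor of insulin-like growth factor, was higher in T_EXE, as was the estrogen-induced PDZK1 (1.61), whose call was lost without T_EXE replicate 4 (adjusted p = 0.062). PGR (0.31, SE 0.32), GREB1 (0.20, SE 0.23) and TFF1 (0.15, SE 0.15) were not called, with intervals of 2 SE either side from -0.33 to 0.95, -0.27 to 0.67 and -0.15 to 0.45. No list was called with all arrays. Leaving out single arrays, calls came for p53 targets without T_ANA replicate 2, 3 or 6 or T_EXE replicate 1, 2 or 3 (adjusted p = 0.00905 to 0.0499), and for DNA replication without all of these in turn but T_EXE replicate 3 (0.0191 to 0.0453). They also came for estrogen-induced genes without T_ANA replicate 3 or 6 or T_EXE replicate 1 or 3 (0.0241 to 0.0482), and for cholesterol biosynthesis without T_ANA replicate 2 or 3 (0.0122 and 0.0411). Mitosis was called without T_ANA replicate 6 (0.0453) and interferon response without T_EXE replicate 1 (0.0241). In all, 643 genes were called, 238 higher and 405 lower in T_EXE, 13 of them at least 2-fold. The count was 416, 245, 357 and 328 without T_ANA replicates 3 to 6, and 310, 300, 408 and 402 without T_EXE replicates 1, 4, 5 and 6. It was 1593 with array weights, and 50 with a random block within groups, 74 with replicates 1 to 3 only and 1665 with replicates 4 to 6 only, chosen after seeing the data.

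Against letrozole, T_EXE had higher PDZK1 (2.49, SE 0.41, adjusted p = 0.000159), CALB2 (2.25, SE 0.50), MAOB (1.94, SE 0.31) and IGSF1 (1.77). AKR1C3 (-3.01, SE 0.41, adjusted p = 1.08e-05), PHLDA1 (-1.72, SE 0.31), F13A1 (-1.65, SE 0.21) and MICB (-1.64) were lower. GREB1 (0.91, SE 0.23) was higher in T_EXE, while PGR (0.96, SE 0.32, adjusted p = 0.0658) and TFF1 (0.47, SE 0.15, adjusted p = 0.0564) were not called. TFF1 was called without T_LET replicate 1 or 3 (adjusted p = 0.0498 and 0.0294). Estrogen-induced genes were higher in 12 of 41, such as CCN5 (1.70), and lower in 1 (adjusted p = 3.49e-08, and p = 0.572 with an estimated correlation). DNA replication genes were lower in 8 of 34, such as GINS2 (-0.74), and mitosis genes in 2 of 36, such as KIF2C (-0.54) (adjusted p = 2.08e-10 and 0.000273, and p = 0.586 and 0.916 with an estimated correlation). p53 target genes were higher in 1 of 16 and cholesterol biosynthesis genes in 2 of 18 (adjusted p = 0.00966 and 0.0464, and p = 0.586 and 0.916 with an estimated correlation), the latter call being lost without T_LET replicate 4 or 6 or T_EXE replicate 1, 4, 5 or 6 (adjusted p = 0.0558 to 0.173). In all, 657 genes were called, 281 higher and 376 lower in T_EXE, 58 of them at least 2-fold. Fitted on the arrays of these groups alone the count was 1326, and 224 with a random block within groups, chosen after seeing the data.

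Without testosterone the steroidal and the non-steroidal inhibitor were further apart. MGP (7.12, SE 0.60, adjusted p = 1.29e-10), GJA1 (6.14, SE 0.71), CA2 (4.81, SE 0.48), PDZK1 (4.59, SE 0.58) and GREB1 (2.99, SE 0.33) were higher in EXE_R than in ANA_R. RLN2 (-3.10, SE 0.43), DKK1 (-2.83, SE 0.45), CYP26B1 (-2.70, SE 0.50) and PKIA (-2.54) were lower. ESR1 (-1.39, SE 0.33) was lower in EXE_R while PTGES (3.50) was higher. TFF1 differed by 0.07 (SE 0.21, interval of 2 SE either side -0.36 to 0.49) and was not called. Estrogen-induced genes were higher in 17 of 41 and lower in none (mean 0.90, adjusted p = 5.37e-09, and p = 0.133 with an estimated correlation). ERK-output genes were higher in 7 of 19, such as EPHA4 (3.15) and DUSP5 (2.74), and IER3 (-2.25) was lower (adjusted p = 0.00105, and p = 0.133 with an estimated correlation). Steroid hormone metabolism genes were higher in 5 of 21, such as AKR1C3 (3.21), and p53 target genes in 4 of 16, such as CDKN1A (1.29) (adjusted p = 0.00134 and 0.00134, and p = 0.133 and 0.267 with an estimated correlation). DNA replication genes were lower in 3 of 34, and the mitosis list was called lower with 0 of 36 members called by limma and 7 at an unadjusted p under 0.05 (adjusted p = 0.00103 and 0.00103, and p = 0.644 and 0.715 with an estimated correlation), the latter call being lost without ANA_R replicate 1 (adjusted p = 0.111). The interferon-response list was called higher on 1 of 31 genes (adjusted p = 0.0172, and p = 0.725 with an estimated correlation), a call lost without EXE_R replicate 2 or ANA_R replicate 1 or 2 (adjusted p = 0.0612, 0.0514 and 0.0759). In all, 1142 genes were called, 535 higher and 607 lower in EXE_R, 261 of them at least 2-fold. The count was 555 without ANA_R replicate 1, 641 without EXE_R replicate 3 and 728 without EXE_R replicate 1, and 601 with a random block within groups, chosen after seeing the data.

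Tamoxifen resistance was set against the mean of the lines resistant to aromatase inhibitors, all with testosterone. TEX14 (3.57, SE 0.12, adjusted p = 3.63e-23), MPPED2 (2.92, SE 0.25), GDAP1 (2.79, SE 0.15) and the adenylate cyclase gene ADCY1 (2.68, SE 0.28) were higher in T_TAM. CA2 (-5.16, SE 0.28, adjusted p = 4.67e-17), KLK11 (-3.90, SE 0.27), AKR1C3 (-3.87, SE 0.33) and MGP (-3.47, SE 0.34) were lower. PGR (1.01) was higher and CCND1 (-0.37) lower in T_TAM, and GREB1 (0.13, SE 0.19) was not called. ERK-output genes were lower in 13 of 19, such as EGR1 (-1.47) and EPHA2 (-1.37), and higher in 2, IER3 (2.46) and MYC (0.65) (adjusted p = 0.000288, and p = 0.113 with an estimated correlation). Estrogen-induced genes were lower in 13 of 41, such as STC1 (-3.24) and EGR3 (-2.98), and higher in 9, such as AGR2 (1.14) (adjusted p = 0.0144, and p = 0.5 with an estimated correlation), a call lost without T_TAM replicate 1 (adjusted p = 0.0546). Steroid hormone metabolism genes were lower in 7 of 21, such as UGT2B15 (-1.34), and higher in 1, and luminal epithelial markers were lower in 7 of 18, such as XBP1 (-0.66), and higher in 2 (adjusted p = 0.00839 and 0.00839, and p = 0.167 and 0.167 with an estimated correlation). p53 target genes were lower in 6 of 16 and higher in 1, and cholesterol biosynthesis genes were higher in 5 of 18 (adjusted p = 0.0352 and 0.0267, and p = 0.494 and 0.494 with an estimated correlation). The p53 call was lost without T_ANA replicate 2 or T_TAM replicate 3 or 4 (adjusted p = 0.0729, 0.0776 and 0.0991), and the cholesterol call without T_ANA replicate 6 or T_TAM replicate 1 (adjusted p = 0.0744 and 0.0546). In all, 1931 genes were called, 862 higher and 1069 lower in T_TAM, 182 of them at least 2-fold. With replicates 1 to 3 only, chosen after seeing the data, 1248 were called.

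Among the testosterone-free lines, ANA_R had higher CYP26B1 (3.11, SE 0.50, adjusted p = 0.000207), the protein kinase A subunit gene PRKAR2B (2.32, SE 0.46), and its inhibitor gene PKIA (2.24, SE 0.40) than LTEDaro. HOPX (-3.27, SE 0.51), S100P (-2.68, SE 0.51), EPAS1 (-2.52, SE 0.48) and DAB2 (-2.45, SE 0.39) were lower. GREB1 (1.97, SE 0.33) and ESR1 (1.38, SE 0.33) were higher in ANA_R, the call of ESR1 being lost without LTEDaro replicate 3 or ANA_R replicate 1 or 2 (adjusted p = 0.108, 0.0601 and 0.0638). Estrogen-induced genes were higher in 9 of 41 and lower in none (adjusted p = 6.64e-08, and p = 0.3 with an estimated correlation). Mitosis genes were higher in 2 of 36 (adjusted p = 9.79e-08, and p = 0.446 with an estimated correlation). Steroid hormone metabolism genes were lower in 3 of 21, a call lost without LTEDaro replicate 3 (adjusted p = 0.0266, adjusted p = 0.32 with an estimated correlation, and adjusted p = 0.127 without that array). Unfolded protein response genes, ERK-output genes and basal markers were lower in 2 each, and p53 targets and drug efflux genes in 1 each (adjusted p = 0.000598, 0.0312, 0.0312, 0.000598 and 0.00946, and p = 0.32, 0.32, 0.32, 0.3 and 0.3 with an estimated correlation). The DNA replication list was called higher on 1 gene, and the interferon-response and estrogen-repressed lists lower with 0 members called by limma and 2 each at an unadjusted p under 0.05 (adjusted p = 0.00457, 0.00276 and 0.0312, and p = 0.501, 0.501 and 0.483 with an estimated correlation). Without LTEDaro replicate 3 the unfolded protein response, DNA replication, basal and interferon calls were lost (adjusted p = 0.0503 to 0.609). The ERK, basal and estrogen-repressed calls were lost without ANA_R replicate 1 or 2 (adjusted p = 0.0669 to 0.21). Without LTEDaro replicate 1 the ERK, estrogen-repressed and drug efflux calls were lost (adjusted p = 0.0565 to 0.307), and the ERK call without replicate 2 (adjusted p = 0.0553). In all, 608 genes were called, 370 higher and 238 lower, 104 of them at least 2-fold. The share of called genes that was higher was 60.9%, against 46.3% with each array centred on its median. The count was 198 and 209 without ANA_R replicates 1 and 2, 949, 940 and 275 without LTEDaro replicates 1, 2 and 3, 185 with a random block within groups, chosen after seeing the data, and 0 by limma on the arrays of these groups alone (968 at an unadjusted p under 0.05).

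EXE_R had higher MGP (6.92, SE 0.60, adjusted p = 8.45e-11), the neuropeptide Y receptor gene NPY1R (6.21, SE 0.69), GJA1 (6.18, SE 0.71), PDZK1 (5.73, SE 0.58) and GREB1 (4.96, SE 0.33) than LTEDaro. CEACAM6 (-4.28, SE 0.62), RFTN1 (-4.06, SE 0.32, adjusted p = 9.63e-12), PTGER4 (-3.71, SE 0.49) and HOPX (-3.68, SE 0.51) were lower. Estrogen-induced genes were higher in 27 of 41 and lower in none, a call that held with an estimated correlation (mean 1.46, adjusted p = 3.44e-20 and 0.0166). Estrogen-repressed genes were lower in 5 of 12, such as IL1R1 (-3.02) (adjusted p = 0.00258, and p = 0.671 with an estimated correlation). PGR (2.70), CCND1 (0.49) and IGF1R (1.78) were higher in EXE_R, and the mitosis and DNA replication lists were not called, though the DNA replication list was called lower without LTEDaro replicate 3 (mean -0.264, adjusted p = 0.000785). In all, 1654 genes were called, 853 higher and 801 lower, 376 of them at least 2-fold. The share higher was 51.6%, against 41.1% with each array centred on its median. The count was 1079 without EXE_R replicate 3, 449 on the arrays of these groups alone, and 976 with a random block within groups, chosen after seeing the data.

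T_ANA and ANA_R are named as lines of their own in the labels, so their comparison is not the effect of adding the hormone. GJA1 (7.07, SE 0.62, adjusted p = 1.97e-10), MGP (5.59, SE 0.52), CA2 (4.80, SE 0.42), KLK11 (4.07, SE 0.40), GREB1 (3.04, SE 0.29) and AKR1C3 (3.53) were higher in T_ANA. CCDC170 (-2.63, SE 0.32), RLN2 (-2.60, SE 0.37), PHACTR2 (-2.23, SE 0.18), SOX2 (-1.88) and ESR1 (-1.42, SE 0.28) were lower. Estrogen-induced genes were higher in 14 of 41, such as PTGES (2.95), and lower in 1 (adjusted p = 1.65e-06, and p = 0.411 with an estimated correlation). ERK-output genes were higher in 7 of 19, such as EPHA4 (2.33), and lower in 1, and interferon-response genes were higher in 4 of 31 (adjusted p = 0.00059 and 0.00456, and p = 0.196 and 0.874 with an estimated correlation). Steroid hormone metabolism genes were higher in 3 of 21 and lower in 1 (adjusted p = 0.0488, and p = 0.411 with an estimated correlation), a call lost without T_ANA replicate 2, 4, 5 or 6 or ANA_R replicate 1 or 3 (adjusted p = 0.0513 to 0.0832). In all, 1619 genes were called, 837 higher and 782 lower, 207 of them at least 2-fold. The count was 524 without ANA_R replicate 1, 785 on the arrays of these groups alone, and 873 with a random block and 959 with replicates 1 to 3 only, both chosen after seeing the data.

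T_ANA minus ANA_R (here testosterone difference, not a hormone response) was tested against T_only minus control, as an interaction. TFF1 (-2.95, SE 0.26) and PGR (-2.22, SE 0.55) had a smaller testosterone difference in the resistant lines, and GREB1 (-0.10, SE 0.41) was not called. CCN5 (4.99, SE 0.71), MAOB (4.88, SE 0.53), APOD (4.66, SE 0.71) and COL5A1 (4.38, SE 0.47) had the highest interactions, having fallen with testosterone in parental cells and not in the resistant lines. CYP26B1 (-5.07, SE 0.62), CCDC170 (-3.65, SE 0.46) and DLGAP5 (-3.48) lay at the other end. All 36 mitosis genes (mean 1.79 in ANA_R against control, 0.005 in T_ANA against T_only) had a lower testosterone difference (mean -1.78, adjusted p = 4.37e-29, and p = 0.104 with an estimated correlation). Of the ERK-output genes 14 of 19 had a higher one, such as EGR1 (3.46) (adjusted p = 2.14e-05, and p = 0.0556 with an estimated correlation). It was lower for 18 of 41 estrogen-induced genes and higher for 7, lower for 18 of 34 DNA replication genes and higher for 1, and lower for 12 of 18 cholesterol biosynthesis genes (adjusted p = 0.00723, 4.85e-05 and 0.000174, and p = 0.417, 0.417 and 0.307 with an estimated correlation). Mesenchymal markers had a higher one in 8 of 19 (adjusted p = 0.00186, and p = 0.307 with an estimated correlation). Interferon-response genes had a higher one in 3 of 31, basal markers in 7 of 15 (2 lower) and steroid hormone metabolism genes in 5 of 21 (2 lower) (adjusted p = 0.0467, 0.0467 and 0.0467, and p = 0.704, 0.307 and 0.307 with an estimated correlation), calls lost on leaving out any of 11, 8 and 10 single arrays (adjusted p = 0.0503 to 0.0926). In all, 3789 genes were called, 1732 above and 2057 below 0, 1137 of them at least 2-fold. With each array centred on its median, the median interaction of all genes was 0.121.

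T_EXE and EXE_R, also named as lines of their own, differed in 30 genes, a count that rests on the setting. The RNA-binding protein gene TAF15 (0.79, SE 0.09, adjusted p = 2.44e-06) and the neuronal growth protein gene BASP1 (1.08, SE 0.22) were higher in T_EXE. AMPD1 (-2.81, SE 0.65) and the gastrin-releasing peptide receptor gene GRPR (-0.64, SE 0.13) were lower. All but TAF15 lost their calls without EXE_R replicate 3 (adjusted p = 0.177 for BASP1 and 0.346 for AMPD1 and GRPR) and without T_EXE replicate 1 or EXE_R replicate 1 or 2 (adjusted p = 0.0506 to 0.124). Calls of BASP1 and AMPD1 were also lost without T_EXE replicate 2 or 3 (adjusted p = 0.0579 to 0.113). The differences of GREB1 (0.24, SE 0.29), PGR (-0.39, SE 0.39) and TFF1 (-0.02, SE 0.18) were not called. Hypoxia-response and glycolysis genes were called as a list, with a mean of 0.17 with 0 of 19 members called by limma and 2 at an unadjusted p under 0.05, and this held with an estimated correlation (adjusted p = 0.0198 and 0.0273) but was lost without T_EXE replicate 4, 5 or 6 (adjusted p = 0.0603, 0.0603 and 0.0601). No other list was called with all arrays. The interferon-response list was called without T_EXE replicate 1 or 2 (adjusted p = 0.0116 and 0.0247), and the cholesterol list without T_EXE replicate 2 or EXE_R replicate 3 (adjusted p = 0.0283 and 0.0262). The estrogen-induced genes had a mean of -0.08. Of the 30 genes 13 were higher and 17 lower, 3 of them at least 2-fold. With array weights 1196 were called, and 2 with a random block within groups, chosen after seeing the data. The count was between 3 without EXE_R replicate 3 and 71 without T_EXE replicate 5. It was 5, 10, 13 and 47 without T_EXE replicates 1, 2, 3 and 6, and 7 and 16 without EXE_R replicates 1 and 2. EXE_R differed from T_EXE replicates 1 to 3 in 762 genes and from replicates 4 to 6 in 3. The share of called genes that was higher, 43.3%, was 54.5% with each array centred on its median.

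Likewise, T_EXE minus EXE_R was lower than T_only minus control for GREB1 (-2.90, SE 0.41), PGR (-3.36, SE 0.55) and TFF1 (-2.87, SE 0.26) and most of all for MGP (-5.88, SE 0.73, adjusted p = 4.82e-07), PDZK1 (-5.05, SE 0.71), TMT1A (-4.33, SE 0.75) and SULF1 (-4.23, SE 0.85). It was higher for L1CAM (3.92, SE 0.41), TAGLN (3.78), APOD (3.77) and TNS3 (3.61, SE 0.42). Estrogen-induced genes had a lower testosterone difference in 22 of 41 and a higher one in 1, and mitosis genes (mean 0.055 between T_EXE and EXE_R) a lower one in 35 of 36, such as ASPM (-2.74) (adjusted p = 2.16e-12 and 9.38e-36, and p = 0.0769 and 0.0769 with an estimated correlation). DNA replication genes had a lower one in 7 of 34 and a higher one in 1, and cholesterol biosynthesis genes a lower one in 5 of 18 (adjusted p = 0.000189 and 0.000122, and p = 0.47 and 0.233 with an estimated correlation). It was higher for 5 of 19 ERK-output genes and lower for 1, and higher for 5 of 23 drug efflux genes and 5 of 19 mesenchymal markers (adjusted p = 0.0126, 0.0215 and 0.00686, and p = 0.233, 0.233 and 0.233 with an estimated correlation), the last call being lost without control replicate 1 (adjusted p = 0.0544). In all, 1673 genes were called, 800 above and 873 below 0, 533 of them at least 2-fold. With a random block within groups, chosen after seeing the data, 1056 were called.

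The difference between the lines resistant to exemestane and to anastrozole was smaller with than without testosterone for MGP (-6.63, SE 0.73, adjusted p = 1.45e-07), GJA1 (-6.10, SE 0.87), CA2 (-4.60, SE 0.59) and GREB1 (-2.80, SE 0.41). For AKR1C3 (-4.25, SE 0.70) it was 3.21 without testosterone and -1.04 with it, the latter not called. The interaction lay above 0 for PHACTR2 (2.54, SE 0.26, adjusted p = 6.22e-08), CCDC170 (2.33, SE 0.46) and LXN (2.09, SE 0.39), which were lower in EXE_R than in ANA_R without testosterone (-2.40, -2.23 and -1.70). Estrogen-induced genes had a lower difference with testosterone in 9 of 41, such as PTGES (-3.11) and PDZK1 (-2.98) (adjusted p = 0.000346, and p = 0.692 with an estimated correlation). ERK-output genes had a lower one in 6 of 19 and a higher one in 1, and steroid hormone metabolism genes a lower one in 3 of 21 and a higher one in 1 (adjusted p = 0.00178 and 0.0134, and p = 0.273 and 0.273 with an estimated correlation). The mitosis list was called higher with 0 members called by limma and 4 at an unadjusted p under 0.05 (adjusted p = 0.0443, and p = 0.792 with an estimated correlation), a call lost without T_ANA replicate 6, T_EXE replicate 1, 2 or 3, EXE_R replicate 3 or ANA_R replicate 1 (adjusted p = 0.223, 0.109, 0.0769, 0.0527, 0.195 and 0.537). In all, 1230 genes were called, 550 above and 680 below 0, 254 of them at least 2-fold. The count was 369 without ANA_R replicate 1, 492 without EXE_R replicate 3 and 812 without EXE_R replicate 1, and 363 with a random block within groups, 501 with replicates 1 to 3 only and 2281 with replicates 4 to 6 only, chosen after seeing the data.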

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

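The tests weighing explanations below were chosen after the results were seen, and the other splits of the arrays had been planned.

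Few genes, 30, differed between T_EXE and EXE_R, against 1619 between T_ANA and ANA_R, but the count rests on the setting, with 397 where replicates 1 to 3 and 4 to 6 were a block of 2 levels, 1196 with array weights, and 762 against T_EXE replicates 1 to 3 beside 3 against replicates 4 to 6, and 1974 genes had an unadjusted p under 0.05. Exchanged labels of single arrays are argued against, since the nearest array of 3 of 3 EXE_R arrays was another EXE_R array. What cannot be told apart is an exchange of the whole EXE_R set with T_EXE replicates 4 to 6, whose mean r with T_EXE replicates 1 to 3 differed by 0.0009, and a comparison unable to show differences, where the SD over genes of the log2 difference was 0.593 times that of the anastrozole lines but replicates of T_EXE pooled together hid differences. Estrogen-like activity of exemestane without testosterone cannot be told apart from other differences of these lines: estrogen-induced genes were higher in EXE_R than in ANA_R and LTEDaro by fry (highest adjusted p 0.000341), but with an estimated correlation camera gave adjusted p = 0.133 and 0.0166, and the rise had been seen before the test. That EXE_R resembled T_EXE replicates 4 to 6 (mean r 0.9923) more than T_EXE replicates 1 to 3 did (0.9875), so that EXE_R and these arrays may stem from related cultures, stays open and untested.

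Replicates 1 to 3 differed from replicates 4 to 6 within the resistant lines with testosterone; an array batch shared by all groups would move the same genes in each, and the median correlation of these differences between groups was 0.04, from -0.32 for T_only and T_ANA to 0.351 for T_EXE and T_TAM. RNA quality cannot be told apart: between replicates 1 to 3 and 4 to 6 the ACTB and GAPDH 3' minus 5' signals differed by 0.043 (SE 0.03) and 0.042 (SE 0.021) in T_EXE, with 771 genes called, and by 0.091 (SE 0.025) and -0.029 (SE 0.044) in T_only, with 0 called by limma and 221 at an unadjusted p under 0.05. T_LET (0.038 and 0.011) and T_TAM (0.04 and -0.004), with smaller differences than T_only, and T_ANA, with the largest of ACTB (-0.112) and 17 genes called, go against it, but within SEs of up to 0.065. Separate sublines could carry changes in runs of neighbouring genes, and 3 of 4 resistant groups had a run beyond all shuffles. Shuffles cannot tell sublines from other causes of shared change, nor can the labels. Batches of single groups, or of some such as T_EXE and T_TAM, stay open, since the labels give no array date.

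ESR1 and its neighbours were raised in ANA_R, with a median of 1.09 over 15 genes. Of 1000 shuffles of gene order 0 gave a run as high. The 15 had medians of -0.031 in EXE_R, where estrogen-induced genes rose, and 0.224 in T_only (3 higher), so estrogen-type regulation of some stays open. Extra copies of the chromosome segment cannot be told apart from other causes of a regional rise. Of the run, 9 of 9 genes above the median signal, ESR1 itself among them, were called higher. But the run was picked for being the highest and no copy number was measured.

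Other splits, fitted on the arrays compared, gave fewer genes for T_only against control (real 4100, highest other 203). This held for T_LET (3696, 1652), T_ANA (3582, 2578), T_EXE (2286, 0) and T_TAM (2243, 12) against T_only. It held for T_EXE against T_ANA (330, 31) and T_LET (1326, 1), T_TAM against the inhibitors (2003, 218) and T_ANA against ANA_R (785, 30). It held for the interactions of anastrozole (3650, 2133) and exemestane (2317, 2264) with parental cells and of exemestane against anastrozole (1309, 1237). Chance stays possible, as replicates may share a culture and splits of the last 2 interactions came near. For T_LET against T_ANA 2 of 100 splits, the real one included, gave as many as its 32 genes, and the highest gave 544; for T_EXE against EXE_R 3 of 84 gave as many as its 63, and the highest, T_EXE replicates 1 to 3 against the rest, gave 2213. Such splits point to a structure among these arrays beyond the groups. The 10 splits of 3 against 3 arrays are too few for a share under 0.05: LTEDaro (606), ANA_R (2453) and EXE_R (3072) against control, EXE_R against ANA_R (1243) and EXE_R against LTEDaro (449) each had 0 in the highest other split, and ANA_R against LTEDaro had 0 in all 10.

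Interactions were tested directly, with 3789 genes called for the anastrozole lines against parental cells, 1673 for the exemestane lines, and 1230 for exemestane against anastrozole with and without testosterone. Among 145 groups of 6 values, single arrays stood apart in 8, where chance gives about 1 in 20. They were TFF1 at 12.5 in T_TAM replicate 2 (nearest other 13.06), GREB1 at 10.75 in T_only replicate 6 (11.28), the mean of estrogen-induced genes at 9.15 in T_ANA replicate 2 (9.57), basal epithelial markers at 6.73 in T_only replicate 6 (6.88), leukocyte markers at 5.55 in T_LET replicate 3 (5.37), steroid hormone metabolism genes at 6.7 and drug efflux and detoxification genes at 7.37 in T_only replicate 3 (6.44 and 7.2), and BCL2-family regulators at 7.71 in T_EXE replicate 4 (7.83).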

How the results depend on the processing

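Planned settings and those added after seeing the data (the random block and fits with part of the replicates) are given together. Of 240 counts from the settings fixed beforehand, other than leaving out an array, 176 stayed within 1.5 times the count given and 64 moved; of 225 leaving out an array 185 and 40, and of 46 added 21 and 25. Of 2280 list results 2038 kept their call or its absence, 187 lost and 55 gained one, and leaving out an array 4097 of 4275 kept theirs or its absence, 96 lost and 81 gained one. Named genes kept their call or its absence in 11255 of 11727 planned, 11460 of 12627 leave-one-out and 1983 of 2492 added results.

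Counts follow the order of the report, naming groups. Without probe sets ending in _x_at or _s_at they were T_only 2443, T_LET 1735, T_ANA 2243, T_EXE 1075, T_TAM 1300, LTEDaro 1555, ANA_R 1804, EXE_R 1379, T_LET against T_ANA 61, T_EXE against T_LET 434, EXE_R against ANA_R 715, T_TAM against the inhibitors 1153, ANA_R against LTEDaro 313, EXE_R against LTEDaro 1012, T_ANA against ANA_R 904, and the interactions of anastrozole 2374, exemestane 952 and the inhibitors 753. With array weights: T_only 6200, T_EXE 3262, T_TAM 3493, LTEDaro 4406, EXE_R 4703, T_LET against T_ANA 1073, T_EXE against T_ANA 1593 and T_LET 1855, EXE_R against ANA_R 2390 and LTEDaro 2839, T_EXE against EXE_R 1196, interactions of exemestane 3850 and the inhibitors 2721. With only the arrays compared: LTEDaro 606, T_LET against T_ANA 32, T_EXE against T_ANA 330 and T_LET 1326, ANA_R against LTEDaro 0 by limma (968 at an unadjusted p under 0.05), EXE_R against LTEDaro 449, T_ANA against ANA_R 785, T_EXE against EXE_R 63. Without dim genes T_EXE against T_ANA had 328 and T_EXE against EXE_R 11, and the latter had 10 after quantile normalization. At 2-fold the counts stand beside each count in the report: 581, 214, 184, 170, 176, 500, 672, 568, 9, 13, 58, 261, 182, 104, 376, 207, 3, 1137, 533 and 254. Shared calls at 2-fold were 119 (T_LET and T_ANA), 97 (T_LET and T_EXE), 71 (T_LET and T_TAM), 113 (T_ANA and T_EXE), 53 (T_ANA and T_TAM), 45 (T_EXE and T_TAM), 343 (LTEDaro and ANA_R), 245 (LTEDaro and EXE_R) and 334 (ANA_R and EXE_R). With T_only split, shared calls at any fold were 1051, 665, 674, 705, 602 and 295 for the pairs with testosterone.

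The replicate numbers do not pair the arrays: 138 same-numbered pairs correlated between -0.635 and 0.5 (median 0.018, 47 over 0.1), and 9 of 42 arrays correlated best with their own number. With a replicate block T_EXE against EXE_R had 349 calls, with replicates 1 to 3 and 4 to 6 as a block of 2 levels 397, and the other counts stayed within 1.5 times. With the random block within groups: T_EXE 1173, T_TAM 1494, LTEDaro 1707, T_LET against T_ANA 11, T_EXE against T_ANA 50 and T_LET 224, EXE_R against ANA_R 601, ANA_R against LTEDaro 185, EXE_R against LTEDaro 976, T_ANA against ANA_R 873, T_EXE against EXE_R 2, interactions of exemestane 1056 and the inhibitors 363. With replicates 1 to 3 only, the others left out of the fit (the 762 of the report comes from a fit of all arrays): T_ANA 1719, T_TAM 1469, T_LET against T_ANA 13, T_EXE against T_ANA 74, T_TAM against the inhibitors 1248, T_ANA against ANA_R 959, T_EXE against EXE_R 686, interaction of the inhibitors 501. With replicates 4 to 6 only: T_EXE 915, T_LET against T_ANA 576, T_EXE against T_ANA 1665, interaction of the inhibitors 2281.

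Leaving out 1 array, the lowest and highest counts were 2437 and 4204 for T_only, 2504 and 3017 for T_LET, 2992 and 3907 for T_ANA, 1396 and 2135 for T_EXE, 1874 and 2434 for T_TAM, 1771 and 2868 for LTEDaro, 2083 and 3169 for ANA_R, 1810 and 2046 for EXE_R, 34 and 200 for T_LET against T_ANA, 245 and 936 for T_EXE against T_ANA, 440 and 616 for T_EXE against T_LET, 555 and 1219 for EXE_R against ANA_R, 1577 and 2093 for T_TAM against the inhibitors, 198 and 949 for ANA_R against LTEDaro, 1079 and 1707 for EXE_R against LTEDaro, 524 and 1910 for T_ANA against ANA_R, 3 and 71 for T_EXE against EXE_R, and 2555 and 4086, 1205 and 1836, and 369 and 1606 for the interactions of anastrozole, exemestane and the inhibitors.

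Directions reversed in 13 results. Without probe sets ending in _x_at or _s_at these were CDC42 in T_EXE against EXE_R (-0.255), COL3A1 in T_LET (-0.009), EGFR in T_EXE (-0.067), ANA_R (0.012) and the exemestane interaction (-0.281), FN1 in T_TAM (0.015) and EXE_R (0.036), NRG1 in T_EXE against T_ANA (-0.056), GAB1 in T_TAM against the inhibitors (-0.048) and TGFB2 in EXE_R against LTEDaro (0.289). EGFR in EXE_R against LTEDaro reversed with array weights (0.78) and without LTEDaro replicate 3 (0.931), and was -0.627 and -1.011 without replicates 1 and 2. DNA replication genes in ANA_R against LTEDaro ranged from -0.017 without LTEDaro replicate 3 to 0.381 without replicate 2.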

Other observations

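Runs of neighbouring genes lower together were found in lines with testosterone against T_only. In T_ANA the run from ERAP1 to MAN2A1 had a median of -0.82, beyond all of 1000 shuffles; it holds the peptide-trimming genes ERAP1 and ERAP2 and the glycan enzyme gene MAN2A1, which was also lower in T_ANA than in T_EXE. By array this run lay at -1.15, -0.78 and -1.05 in T_ANA replicates 4 to 6 and at -0.32, -0.37 and -0.44 in replicates 1 to 3, near the control (-0.4, -0.3 and -0.37). In T_TAM the run from LAMB4 to CAV1 had a median of -0.72 and in T_EXE the overlapping run from NRCAM to MET had a median of -0.53 (0 shuffles as low for each). The T_TAM run holds the caveolin genes CAV1 and CAV2 and the chaperone gene DNAJB9, so these members of the basal epithelial and unfolded protein response lists lie within it. By array that run lay between -0.37 and -0.82 in T_TAM, at -0.58, -0.7 and -0.49 in T_EXE replicates 1 to 3 and at -0.09, -0.07 and -0.04 in replicates 4 to 6. The control lay below T_only as well, at -0.71, -0.3 and -0.31, so the run is not particular to the resistant lines.

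Among the testosterone-free lines, LTEDaro replicates 1 and 2 correlated with ANA_R at a mean r of 0.9876 across genes, and with LTEDaro replicate 3 at 0.9619. ESR1 and its neighbours followed the same division, with medians of 0.68 and 0.71 in LTEDaro replicates 1 and 2 and -0.11 in replicate 3.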
